A study of Arabidopsis thaliana with 6 samples.

How the data were processed

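RNA-seq libraries came from whole seedlings of 2 genotypes, 3 biological replicates each per the labels. Per the labels' protocols, total RNA was depleted of ribosomal RNA with a plant leaf kit, turned into cDNA with a SMARTer PCR kit and sequenced in pairs of 100 bp. Strand marking is not given in the sources used here, so reads from a gene and an antisense partner cannot be told apart. The submitters' processing notes name CASAVA 1.8.2, Trim Galore 0.4.0, TopHat2 2.0.14, Cuffdiff 2.2.1.3, SAMtools and the genome build TAIR10; options and the treatment of reads with several possible origins are not given in the sources used here.

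The authors deposited FPKM (fragments scaled by transcript length and by mapped fragments) per gene and per transcription start group, with 1 value per genotype over its replicates, in the layout of Cuffdiff per the file headers. The authors also deposited a p-value and a q-value for each feature; the lowest p-value is 5.00e-05, shared by 1411 genes, all with q = 6.39e-04. FPKM of a short gene depends strongly on the fragment length model, and a locus can be a bundle of overlapping genes. The deposited log2 ratio column holds spreadsheet errors, so log2 ratios were recomputed from the deposited FPKM, and 7 gene symbols turned into dates were replaced through the reference names. Of 33557 genes, 18038 carried a test, 15512 were not tested and 7 exceeded the depth that Cuffdiff handles. A deposited coverage table gives, for each library, the signal that SAMtools bedcov reports, the sum of per-base read depth over a region, as whole numbers with no scaling by library size or region length. It covers 75 snRNA regions of 25 to 196 bp and a 50 bp extension after each 3′ end. A read that covers a whole extension adds 50 and one that crosses its edge adds less, so low sums stand for very few reads. Of the extensions, 18 were at 0 in all 6 libraries, as were 9 snRNA regions.

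Coordinates are those of the files, TAIR10, counted from 1. A RefSeq annotation of the related assembly TAIR10.1 served only for names, strands and neighbours: 32809 genes matched it by locus, the coding span of 95.9% of 26687 protein-coding genes lay inside the deposited locus, and all 59 snRNA regions of the 5 large families not marked as pseudogenes shared a 20 bp word with another member there. 7 pairs of snRNA regions had identical sequence.

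Summed depth was tested with limma 3.58.1 in R 4.3.3 on log2(depth + 1), genotype as the sole term, no filter and no scaling, with Benjamini-Hochberg adjustment over 150 regions. A log2 difference is on that scale and understates the change of low regions, and where wild type is at 0 it depends on the pseudocount, so depths are given. On data simulated from 123 regions with a known change, the test recovered 14.7% of changes of 3 and 67.6% of changes of 6 on the log2 scale, with 2.64% of its calls false. The simulation drew normal values with 1 SD of 2.25 for every region and left out regions at 0 in all libraries. Real standard errors of regions with reads ran from 0.043 (atU1-12p extension) to 5.8 (atU5-13), and many depths were 0. The simulated shares therefore do not carry over to the calls made here. atU5-13 was left out of the library and family sums after its values were seen, because its mean depth per base was equal in both its regions in 3 libraries, at up to 1250. The pseudogene copy atU4-11p showed the same in 2 wild type libraries, at 2 and 4 per base, and was kept. Group means of library sums and of mean log2 depth were compared with exact 2-sided permutation tests; intervals are at 95%. For genes and start groups the authors' test was used as deposited at q under 0.05, since 1 value per genotype allows no test of its own. Gene lists were tested with Fisher's exact test, 2-sided, for higher and lower calls against the other tested genes, adjusted over 54 tests; genes are not independent replicates. On simulated lists of 25 among 18038 genes, the test passed in 5.00% of lists with the background share and in 100% of lists with a share of 50.0%. Each list's median log2 ratio was set against 10000 random lists matched in 20 classes of mean FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

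The tests, the gene lists and the naming rule were fixed before the data were examined. The lists were the CPL family, RNA polymerase II and its C-terminal domain enzymes, 3′ end processing and snRNA promoter factors, splicing factors, osmotic, salt and ABA response, ion transport, xenobiotic detoxification, heat shock, rapid stress transcription factors, salicylic acid defence and camalexin, jasmonate, flavonoid and anthocyanin, nuclear photosynthesis, root markers, cell division, circadian clock, iron, and auxin. Rules gave plastid-encoded, mitochondrion-encoded, snRNA, snoRNA, tRNA, rRNA, transposable element, cytosolic ribosomal protein and snRNA-downstream genes. Of the hand-written members, 311 were matched by symbol and 7 by locus. The transposable element list holds pseudogenes whose reference note names a transposon. The cytosolic ribosomal protein list holds 19 genes picked by the wording of their reference product name, so it does not stand for the whole class. Named were the CPL genes, up to 4 called members of each list with the largest log2 ratio, the 10 highest and 10 lowest called genes with the larger FPKM at least 5 and neither at 0, called snRNA-downstream genes, the 10 regions with the smallest limma p with the regions of the snRNAs before those genes, and genes with opposite start groups. Further clock genes, the higher photosynthesis genes, FER3, FER4, the U12 regions, atU5-13, the atU6-5 extension, AT1G61280, AT1G70185, NDB4 and the examples from lists added later were named after their values were seen. Single members of the added DNA damage list are not reported here.

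Alternatives were median-ratio scaling of the libraries, pseudocounts of 0.1 and 10, dropping the regions of lowest mean depth, a replicate block, limma's trend and robust settings, depth per base, leaving out each library, q thresholds of 0.01 and 0.1, a 2-fold minimum, FPKM minima of 1 and 5, dropping features listed at 0, recomputed adjustment, windows of 0.5 and 5 kb and control neighbours. Spike-in or library totals were not used here, so absolute depth between libraries cannot be fixed.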

Results

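Total RNA from whole 10-day-old Arabidopsis thaliana seedlings was depleted of ribosomal RNA and sequenced in 6 libraries, 3 from the Columbia wild type and 3 from plants labelled as a CPL4 knockdown made by RNA interference. CPL4 is a phosphatase that acts on the C-terminal domain of RNA polymerase II. The series title asks how CPL4 and salt stress govern a switch from small nuclear RNA (snRNA) to messenger RNA transcription, and these 6 libraries cover the genotype part. snRNAs are short non-coding RNAs of the spliceosome, and their primary transcripts normally end shortly after the mature 3′ end. The deposited files held summed read depth in each library over 75 snRNA regions and over the 50 bp after the 3′ end of each, here called extensions. They also held 1 FPKM value per genotype, a p-value and a q-value for each gene and each transcription start group. Library totals were not given in the sources used here, so depth was known only over the snRNA regions. Summed depth over these regions, leaving out atU5-13, ranged from 2179464 to 7534954 in wild type and from 274395 to 2718072 in the libraries labelled CPL4 knockdown.

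The target transcript did not go down in the libraries labelled CPL4 knockdown. CPL4 (AT5G58003, chromosome 5, 23479804 to 23482048, TAIR10) stood at 4.92 FPKM in wild type and at 8.84 FPKM in the labelled knockdown in the authors' deposited table, a log2 ratio of 0.85 with q = 6.39e-04. CPL1 (log2 ratio 0.57, q = 0.00166) and CPL3 (log2 ratio 0.37, q = 0.0327), related phosphatases, also rose according to the authors' deposited table. CPL2 had a log2 ratio of 0.35 and q = 0.0572 in the authors' deposited table. Of the 4 family members, 3 were called higher, and 4 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0387, and from 0.00805 to 1 over 5 alternatives). CPL4 itself is among the 4, so this test rests in part on the target's own value. The deposited tables gave no value of CPL4 for a single library. Because the target went against its label, "labelled knockdown" below means the libraries labelled CPL4 knockdown, and every direction is drawn from those labels.

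Reads past the 3′ ends of snRNAs were far more abundant in the labelled knockdown than in wild type. The extensions, without atU5-13, summed to 825 ± 167 (SD, n = 3) in wild type and to 15009 ± 5946 (SD, n = 3) in the labelled knockdown (exact 2-sided permutation p = 0.1). With atU5-13 they summed to 842 ± 145 (SD, n = 3) in wild type and 47393 ± 37251 (SD, n = 3) in the labelled knockdown (exact 2-sided permutation p = 0.1). The lowest labelled-knockdown library held 9016 and the highest wild type library 1003. Relative to the depth of the snRNAs themselves, extension depth was 0.0207% ± 0.0101 (SD, n = 3) in wild type and 1.70% ± 1.38 (SD, n = 3) in the labelled knockdown, whose mean was 0.901% without replicate 3, the library of lowest snRNA depth. Summed extension depth was higher in every large family, by 35.3-fold after U1, 17.9-fold after U2, 15.6-fold after U4, 9.52-fold after U5 and 3.55-fold after U6, again without atU5-13. The wild type U5 sums behind this were 188, 30 and 100. With atU5-13, U5 extensions stood at 123 ± 106 (SD, n = 3) in wild type and 33393 ± 31467 (SD, n = 3) in the labelled knockdown. The U4 value depends on atU4-11p, without which U4 extensions stood at 27.7 ± 28.7 (SD, n = 3) in wild type and 1992 ± 875 (SD, n = 3) in the labelled knockdown, 72.0-fold. That fold is loose, since the wild type sums were 5, 60 and 18. The U6 value rests mainly on the atU6-5 extension, at 0, 0 and 18 in wild type and 476, 456 and 189 in the labelled knockdown. The U6 extension sums were 37, 253 and 183 in wild type and 624, 718 and 339 in the labelled knockdown. Single U6 extensions with reads had log2 differences from −2.13 to 7.02, with a median of 0.59. The family sums did not overlap between the groups for any of these 5 families, for U6 only with atU6-5. Each gave an exact 2-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow.

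**Figure D1:**
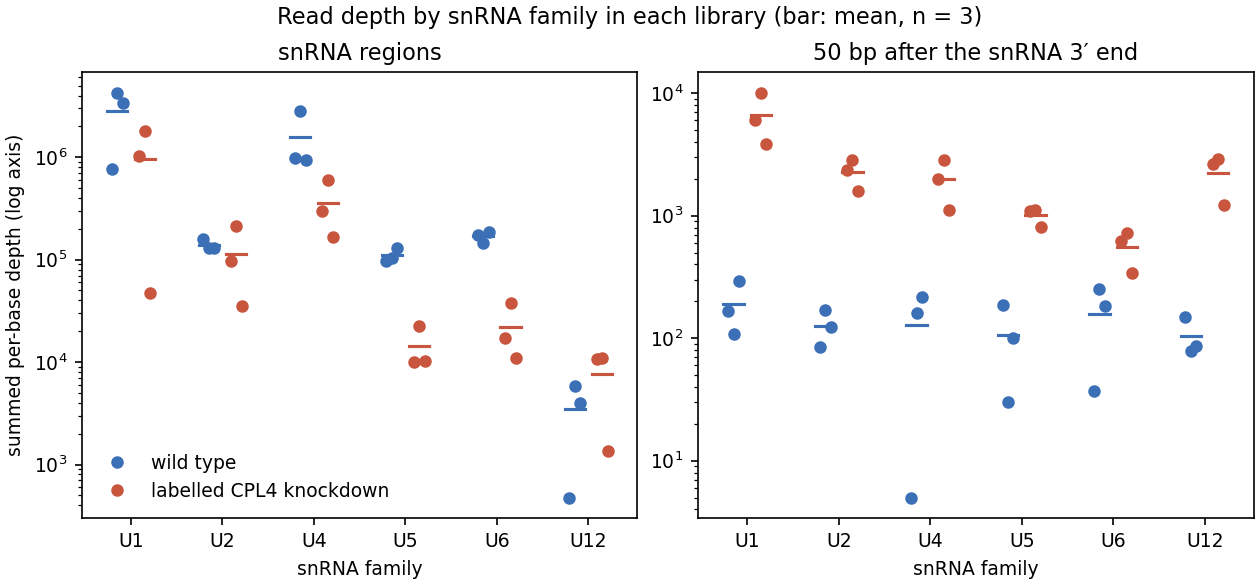
Summed per-base depth (log axis) by snRNA family in each of the 6 libraries, over the snRNA regions (left) and over the 50 bp after their 3′ ends (right), without atU5-13; points are libraries and bars are group means. In the right panel all 3 labelled-knockdown libraries lie above all 3 wild type libraries for every family shown, and in the left panel the groups part for U4, U5 and U6 but overlap for U1, U2 and U12.

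Of the 150 regions, 15 extensions rose and 0 fell in the labelled knockdown (limma, Benjamini-Hochberg adjusted p under 0.05), against 22 and 0 at an unadjusted p under 0.05. The extension of atU2-14 (chromosome 1, 4842473 to 4842522, TAIR10) was listed at 0 in all wild type libraries and had a summed depth of 248 ± 53.3 (SD, n = 3) in the labelled knockdown, with a limma adjusted p = 2.59e-05. The atU2-11 extension (chromosome 1, 3180491 to 3180540) stood at 0 against 436 ± 254 (SD, n = 3; limma adjusted p = 8.84e-04), and that of atU1-3 (chromosome 5, 20996924 to 20996973) at 0 against 157 ± 85.2 (SD, n = 3; limma adjusted p = 8.84e-04). After the pseudogene copy atU1-12p (chromosome 4, 12298739 to 12298788), depth was 0 in wild type and 47.7 ± 2.08 (SD, n = 3) in the labelled knockdown (limma adjusted p = 6.25e-07), about the depth that 1 read over the whole extension gives. None of these 4 extensions overlapped a locus of the deposited gene table. The atU4.1 extension (chromosome 5, 19885541 to 19885590), which also overlapped none, rose from 1.00 ± 1.73 to 621 ± 267 (SD, n = 3; limma adjusted p = 0.00290). The atU2.3 extension (chromosome 3, 21397373 to 21397422) rose from 1.00 ± 1.73 to 306 ± 164 (SD, n = 3; limma adjusted p = 0.00584) and lay in the locus of U2.3 itself and of AT3G57770 on the opposite strand. The atU2.7 extension (chromosome 5, 24713358 to 24713407), within the locus of U2.7 and of MIM on the same strand, stood at 0 against 230 ± 103 (SD, n = 3; limma adjusted p = 4.37e-04). Copies within a family are near-identical, and how reads with several possible origins were placed is not given in the sources used here, so the assignment to single copies is uncertain.

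Summed depth over the snRNAs themselves was compared by family. With atU5-13 left out, U5 depth was 7.83-fold lower, U6 depth 7.70-fold and U4 depth 4.48-fold, with no overlap between the groups (exact permutation p = 0.1 each). The U6 sums were 175126, 144179 and 188059 in wild type and 17097, 37752 and 11016 in the labelled knockdown. U2 depth was 139477 ± 16931 (SD, n = 3) in wild type and 114365 ± 89614 (SD, n = 3) in the labelled knockdown (exact permutation p = 0.7). U12 depth was 3452 ± 2733 (SD, n = 3) in wild type and 7644 ± 5459 (SD, n = 3) in the labelled knockdown (exact permutation p = 0.3). With atU5-13, whose mean depth per base was equal in its snRNA region and its extension in 2 labelled-knockdown libraries, U5 depth was 111343 ± 17707 (SD, n = 3) in wild type and 98416 ± 87401 (SD, n = 3) in the labelled knockdown (exact permutation p = 0.8). Among single regions, 17 fell and 0 rose (limma), 8 of them U5 and 6 of them U6, against 27 and 0 at an unadjusted p under 0.05. atU5-8 (chromosome 3, 9225855 to 9225979) fell from 5619 ± 1163 to 343 ± 38.6 (SD, n = 3; limma adjusted p = 5.06e-04). atU5.1b (chromosome 3, 20725777 to 20725902), inside the locus of AT3G55850 on the same strand, fell from 7943 ± 596 to 816 ± 210 (SD, n = 3; limma adjusted p = 8.96e-04). atU5-7 (chromosome 4, 1114505 to 1114630) fell from 917 ± 238 to 148 ± 11.1 (SD, n = 3; limma adjusted p = 0.00234). The mean log2 difference was −1.65 over the snRNA regions and 2.79 over the extensions (exact 2-sided permutation p = 0.1 for each mean).

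Library totals would be needed to set the snRNA regions of different libraries on 1 scale. Scaling by each library's median ratio, which rests on the 54 snRNA regions and 6 extensions with reads in every library and so centres the snRNA regions by construction, moved the median log2 difference of the 123 regions with reads from −0.69 to 0.97. It left 2 snRNA regions lower and 2 higher, with 18 extensions higher and 0 lower, so that the calls went from 15 higher and 17 lower to 20 higher and 2 lower. Under that scaling, which gives extensions relative to snRNA regions, the mean log2 difference of the extensions was 3.33, the family median turned from −0.73 to 0.97 for U2, and U5 (−1.61) and U6 (−1.54) stayed below U2. With 1 library left out, the lower snRNA regions numbered 8, 5 and 7 without wild type replicate 1, 2 and 3, and 6 without labelled-knockdown replicate 1. All regions called then numbered 17 without wild type replicate 2 and 18 without labelled-knockdown replicate 1.

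**Figure D2:**
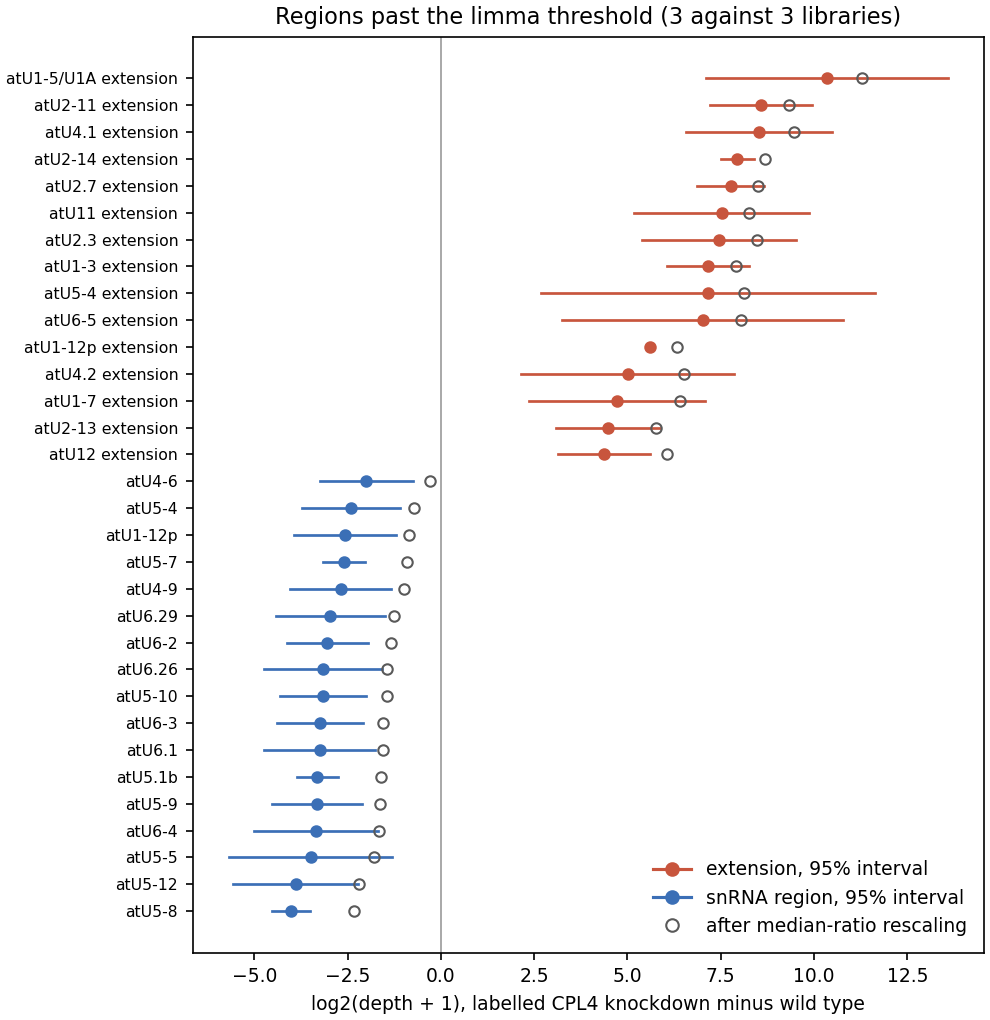
log2 difference in summed depth (pseudocount 1), labelled knockdown minus wild type, with 95% intervals from limma, for the 32 regions past the threshold; open circles are the differences after median-ratio scaling. The 15 extensions lie to the right of 0 under both scalings, and the 17 snRNA regions lie to the left, closer to 0 after scaling.

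Genes next to snRNA genes were examined because transcription past an snRNA can run into its neighbour. Of 18 tested protein-coding genes that begin within 2 kb after an snRNA on the same strand, 3 were called higher and 0 lower in the labelled knockdown, and 2 higher when adjusted over the list alone (Fisher's exact test, adjusted p = 0.806). MTHSC70-2 (AT5G09590, chromosome 5, 2975548 to 2978750), a mitochondrial heat shock protein gene 228 bp after atU2.5, rose from 15.9 to 32.9 FPKM in the authors' deposited table (q = 6.39e-04). AT5G61450, 397 bp after atU2.7, rose from 4.74 to 6.92 FPKM, and AT4G02530, 346 bp after atU5-7, from 61.3 to 78.2 FPKM, both in the authors' deposited table. These 3 distances run to gene boundaries of the RefSeq annotation and differ from the gaps to the deposited loci. The atU2.7 extension was among those that rose. The atU2.5 extension had summed depths of 31, 0 and 11 in wild type and of 110, 234 and 239 in the labelled knockdown, with a limma adjusted p = 0.101. That of atU5-7 had reads in 1 library, at a summed depth of 50 (limma adjusted p = 0.560). The largest log2 ratio of the 18, 6.30, was that of AT1G61280 after atU12, which was not called (q = 0.110) in the authors' deposited table. In a set chosen later, 3 tested genes followed an snRNA whose extension was called higher, and 1 of them was called higher. At an unadjusted p under 0.05, 7 of the 18 were higher and 2 lower. Their median log2 ratio was 0.29, at percentile 99.6 of 10000 random lists of like expression, beside 99.3 for the RNA polymerase II list and 100 for snoRNA genes, lists that did not pass Fisher's exact test either. In the nested windows the median was 0.45 for the 11 tested genes within 0.5 kb and 0.18 for the 31 within 5 kb, at percentiles 99.8 and 98.5. The median was 0.08 for genes downstream on the opposite strand, −0.10 after snoRNA genes, 0.03 after tRNA genes and −0.00 upstream on the same strand, at percentiles from 26.8 to 81.7.

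Across the transcriptome, 18038 genes were tested in the authors' deposited table, and 4060 were called at q under 0.05, with 2295 higher and 1765 lower in the labelled knockdown. At least a 4-fold change was listed for 193 genes called higher and 65 called lower in the authors' deposited table. The largest rises included a pair of MATE efflux carriers, AT2G04070 (chromosome 2, 1353755 to 1355790), which went from 0.0879 to 22.8 FPKM, and AT2G04050 (DTX3), from 0.307 to 39.9 FPKM, in the authors' deposited table. The RING finger gene AT5G60250 was 75.2-fold higher, the transcription factor gene NAC044 51.9-fold, the seed storage protein gene CRA1 34.7-fold and AT3G46890 26.5-fold in the authors' deposited table. UGT74E2 (24.4-fold) and UGT73C1 (23.4-fold), which encode glucosyltransferases, the oxidative stress marker AT2G21640 (23.4-fold) and the receptor-like kinase gene CRK37 (21.0-fold) completed the 10 largest rises by the naming rule in the authors' deposited table. Of the rises given as folds, AT2G21640 stood at 1.23 FPKM in wild type in the authors' deposited table. The others stood at 0.216 to 0.312 FPKM there, so their folds rest on very low wild type values and are loose. AT3G44215, of unknown function, fell from 7.90 to 0.0297 FPKM and AT3G01345 from 10.3 to 0.187 FPKM in the authors' deposited table. AT3G16670 (13.0-fold), the copper amine oxidase gene AT1G31690 (7.24-fold), the F-box gene AT1G73120 (5.63-fold) and the triterpene gene CYP708A2 (4.84-fold) were lower in the authors' deposited table. So were AOP2 (5.01-fold), a glucosinolate gene, and SRG3 (4.39-fold) in the authors' deposited table. U4.2 (5.75-fold) and AT4G23420 (5.37-fold) were also among the 10 largest falls by the naming rule, which leaves out genes listed at 0 in either group and genes below 5 FPKM in both, in the authors' deposited table, and the locus of each holds an snRNA region, atU4.2 and atU1-2.

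Fast stress regulators and salicylic acid defence genes were called higher more often than other tested genes. Of 10 rapid stress transcription factors, 8 were called higher and 0 lower, the same when adjusted over the list alone (Fisher's exact test, adjusted p = 1.30e-04). WRKY46 was 8.96-fold higher, ZAT12 6.74-fold, ZAT10 4.51-fold and WRKY40 3.03-fold in the authors' deposited table. Of 16 genes of salicylic acid defence and camalexin synthesis, 8 were called higher and 2 lower, the same when adjusted over the list alone (adjusted p = 0.00456). PR1, the standard marker of this pathway, went from 4.52 to 88.2 FPKM, and its upstream regulators SARD1 (7.13-fold) and CBP60G (5.16-fold) rose too in the authors' deposited table. The camalexin gene CYP71A13 fell from 1.28 to 0.243 FPKM in the authors' deposited table. Xenobiotic detoxification genes were called higher in 8 and lower in 2 of 25, the same when adjusted over the list alone (adjusted p = 0.0446, and from 6.26e-04 to 0.131 over 5 alternatives). Besides DTX3 and UGT74E2, DTX1 (11.7-fold) and the transporter gene ABCB4 (4.59-fold) led this list in the authors' deposited table. Flavonoid and anthocyanin genes were called higher in 5 and lower in 1 of 11, and 6 and 1 when adjusted over the list alone (adjusted p = 0.0387, and from 0.0212 to 0.634 over 5 alternatives). Its leading members were DFR (5.14-fold), LDOX (3.82-fold), TT4 (3.76-fold) and F3H (1.98-fold) in the authors' deposited table.

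Iron genes and mitochondrion-encoded genes were called higher more often than other tested genes. Of 9 iron deficiency and storage genes, 5 were called higher and 1 lower, the same when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0181, and from 0.0181 to 0.134 over 5 alternatives). The root iron uptake genes FRO2 (2.98-fold) and IRT1 (2.90-fold) and the coumarin gene F6'H1 (2.02-fold) rose, while the regulator BHLH101 fell from 3.37 to 1.65 FPKM in the authors' deposited table. The higher calls were not of uptake genes alone. Of the storage genes, FER4 was called higher (log2 ratio 0.47, q = 0.0128) and FER3 was not called (−0.06, q = 0.817) in the authors' deposited table. Of 53 mitochondrion-encoded genes, 15 were called higher and 2 lower, and 16 and 2 when adjusted over the list alone (adjusted p = 0.0181, and from 0.00310 to 1 over 5 alternatives). The open reading frames ORF117 (4.19-fold) and ORF110A (3.14-fold) and ORF240A, from 106 to 265 FPKM, rose and ORF107A fell from 1309 to 578 FPKM in the authors' deposited table. Plastid-encoded genes were called higher in 5 and lower in 3 of 87, and 3 and 2 when adjusted over the list alone (adjusted p = 0.165 and 0.152). RPS12 rose from 2649 to 7926 FPKM, and the lower ones, the tRNA genes TRNR.1, TRNC and TRNG.2, were listed at 0 in the labelled knockdown in the authors' deposited table.

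Jasmonate, photosynthesis and cell division genes were called lower more often than other tested genes. Of 18 jasmonate genes, 8 were called lower and 3 higher, and 9 and 3 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00265, and from 0.00265 to 0.0622 over 5 alternatives). The response genes VSP1 (from 3.84 to 0.797 FPKM), VSP2 (from 22.1 to 7.75 FPKM) and TAT3 (from 4.29 to 1.41 FPKM) fell, and the synthesis gene LOX4 rose 3.28-fold in the authors' deposited table. Of 27 nuclear photosynthesis genes, 10 were called lower and 3 higher, and 12 and 3 when adjusted over the list alone (adjusted p = 0.00265, and from 0.00159 to 1 over 5 alternatives), and no lower call reached 2-fold. PSAF went from 2126 to 1231 FPKM, LHCB1.3 from 15003 to 9631, LHCA4 from 4656 to 3030 and PSAG from 1975 to 1320 FPKM in the authors' deposited table. The higher members, named after their values were seen, were RBCS2B (log2 ratio 0.51), RBCS3B (0.47) and PSBO2 (0.54) in the authors' deposited table. Cell division and DNA replication genes were called lower in 7 and higher in 1 of 18, and 8 and 2 when adjusted over the list alone (adjusted p = 0.00920, and from 0.00920 to 1 over 5 alternatives), again with no lower call of 2-fold. The mitotic genes CDC20.1 (log2 ratio −0.90), CYCB2;2 (−0.89) and KN (−0.77) fell, and the cyclin gene CYCB1;1 rose (0.93), in the authors' deposited table.

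Clock genes moved in both directions, with 7 of 18 called higher and 7 lower, and 8 and 7 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0284 and 0.00920). Those called higher were LHY (16.0-fold), PRR9 (3.58-fold), CCA1 (2.62-fold), RVE8, RVE1, CDF1 and LNK1 in the authors' deposited table, genes that peak in the morning. Those called lower were PRR3 (from 14.7 to 5.04 FPKM), ELF4, TOC1, FKF1, ELF3, LUX and PRR7 in the authors' deposited table, which peak later in the day except that PRR7 peaks before noon. Over 5 alternatives the adjusted p ranged from 0.0212 to 0.105 for the higher calls and from 0.00310 to 0.768 for the lower ones. The hour of harvest is not given in the sources used here, so its share in these calls and in those of other lists is unknown.

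**Figure D3:**
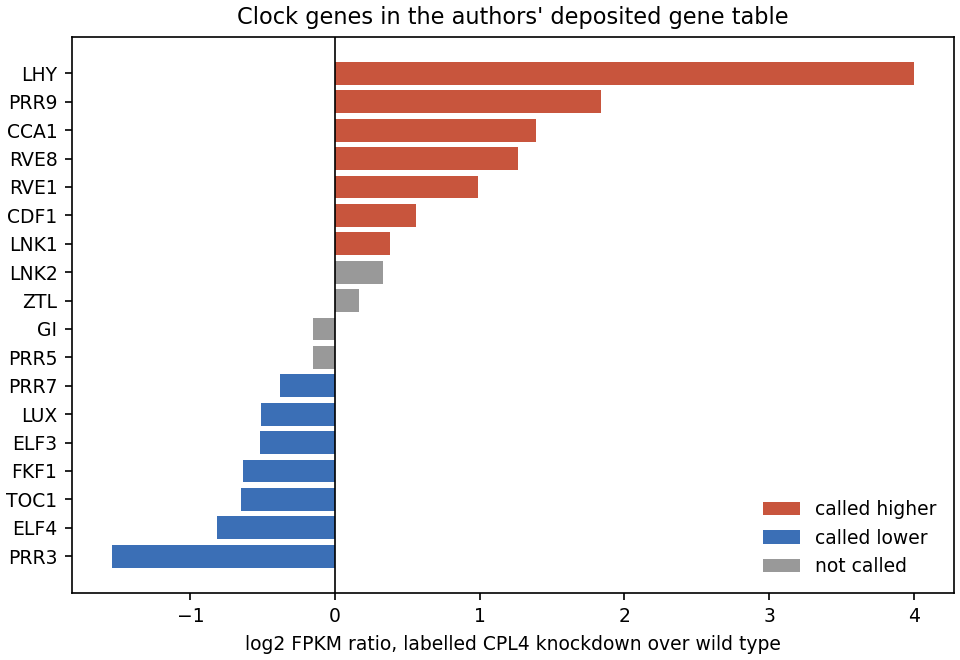
log2 ratio of FPKM, labelled knockdown over wild type, for the 18 clock genes of the authors' deposited table; each bar is 1 gene, with 1 value per genotype and so no error bar, coloured by whether the authors' q was under 0.05. LHY stands furthest to the right at 4.00 and PRR3 furthest to the left at −1.54.

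The other lists did not pass the test. Of 17 RNA polymerase II subunits and C-terminal domain kinases or phosphatases, 5 were called higher and 1 lower, and 6 and 1 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.166). The largest subunit gene NRPB1 rose from 33.5 to 106 FPKM, NRPB7 from 4.71 to 8.28 and NRPB4 from 23.9 to 35.4 FPKM, and the phosphatase gene SSU72 fell (log2 ratio −0.60), in the authors' deposited table. None of 11 tested 3′ end processing and snRNA promoter factors was called, 0 over all genes and 0 when adjusted over the list alone (adjusted p = 0.724 and 0.898), against 1 higher and 1 lower at an unadjusted p under 0.05 from Cuffdiff. Splicing factors were called higher in 4 and lower in 2 of 31, the same when adjusted over the list alone (adjusted p = 1), among them STA1 (2.09-fold higher), SKIP (1.47-fold), SUS2 (1.42-fold) and SCL30 (log2 ratio −0.53) in the authors' deposited table. Osmotic, salt and ABA genes were called higher in 7 and lower in 6 of 27, and 10 and 8 when adjusted over the list alone (adjusted p = 0.207 and 0.152). RD20 rose 7.89-fold and HB-7 2.65-fold, while KIN2 (log2 ratio −1.64) and COR15B (−1.59) fell in the authors' deposited table. Of 5 ion transport genes, 1 was called lower, the same when adjusted over the list alone (adjusted p = 0.724), the sodium transporter gene HKT1 (from 1.98 to 0.990 FPKM) in the authors' deposited table. Heat shock genes were called higher in 3 and lower in 1 of 10, the same when adjusted over the list alone (adjusted p = 0.305), with HSP70 at 3.93-fold, HSP90.1 at 2.63-fold, HSP23.6-MITO going from a listed 0 to 1.14 FPKM and HSP70T-2 at a log2 ratio of −0.67 in the authors' deposited table. Auxin response genes were called higher in 3 and lower in 1 of 6, the same when adjusted over the list alone (adjusted p = 0.118), namely GH3.3 (1.81-fold), GH3.5 (1.67-fold), IAA2 (log2 ratio 0.38) and IAA29 (log2 ratio −1.25) in the authors' deposited table. Root markers, included to show a shift in tissue share, were called higher in 1 (SHR) and lower in 2 (CASP1 and CASP2) of 6, the same when adjusted over the list alone (adjusted p = 0.886 and 0.283).

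Non-coding and repeat classes did not pass either. snRNA genes were called higher in 2 (U2.2 and U12) and lower in 2 (U4.2 and U2.5) of 12, the same when adjusted over the list alone (Fisher's exact test, adjusted p = 0.922 and 0.688). U12 rose from 52.5 to 94.1 FPKM, U2.2 from 7.34 to 17.5 and U2.5 fell from 69.5 to 49.5 FPKM in the authors' deposited table, where a locus can span overlapping genes. snoRNA genes were called higher in 5 and lower in 1 of 35, the same when adjusted over the list alone (adjusted p = 1 and 0.544), with AT3G24615 (5.24-fold), U3D (2.96-fold) and AT2G35387 (2.13-fold) higher and AT1G75163 listed at 0 in the labelled knockdown in the authors' deposited table. Of 5 tested tRNA genes 1 was called lower, the same when adjusted over the list alone (adjusted p = 0.724), AT4G18725, listed at 0 in the labelled knockdown in the authors' deposited table. The 1 tested rRNA gene was not called over all genes and was called higher when adjusted over the list alone (adjusted p = 1). Transposable element genes were called lower in 4 and higher in 1 of 12, and 5 and 1 when adjusted over the list alone (adjusted p = 0.0989). SADHU3-2 (5.89 FPKM in wild type), SADHU3-1 (2.31 FPKM) and SADHU5-2 (1.13 FPKM) were listed at 0 in the labelled knockdown, and SADHU1-3 rose 1.86-fold, in the authors' deposited table. The cytosolic ribosomal protein list, matched by product name, held 19 genes and does not stand for the whole class. Of its 14 tested genes, 4 were called higher and 0 lower, and 6 and 2 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.248). It was led by AT4G00810 (1.55-fold), AT4G25890 (1.46-fold), AT2G27710 (1.32-fold) and AT5G47700 (1.31-fold) in the authors' deposited table.

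**Figure D4:**
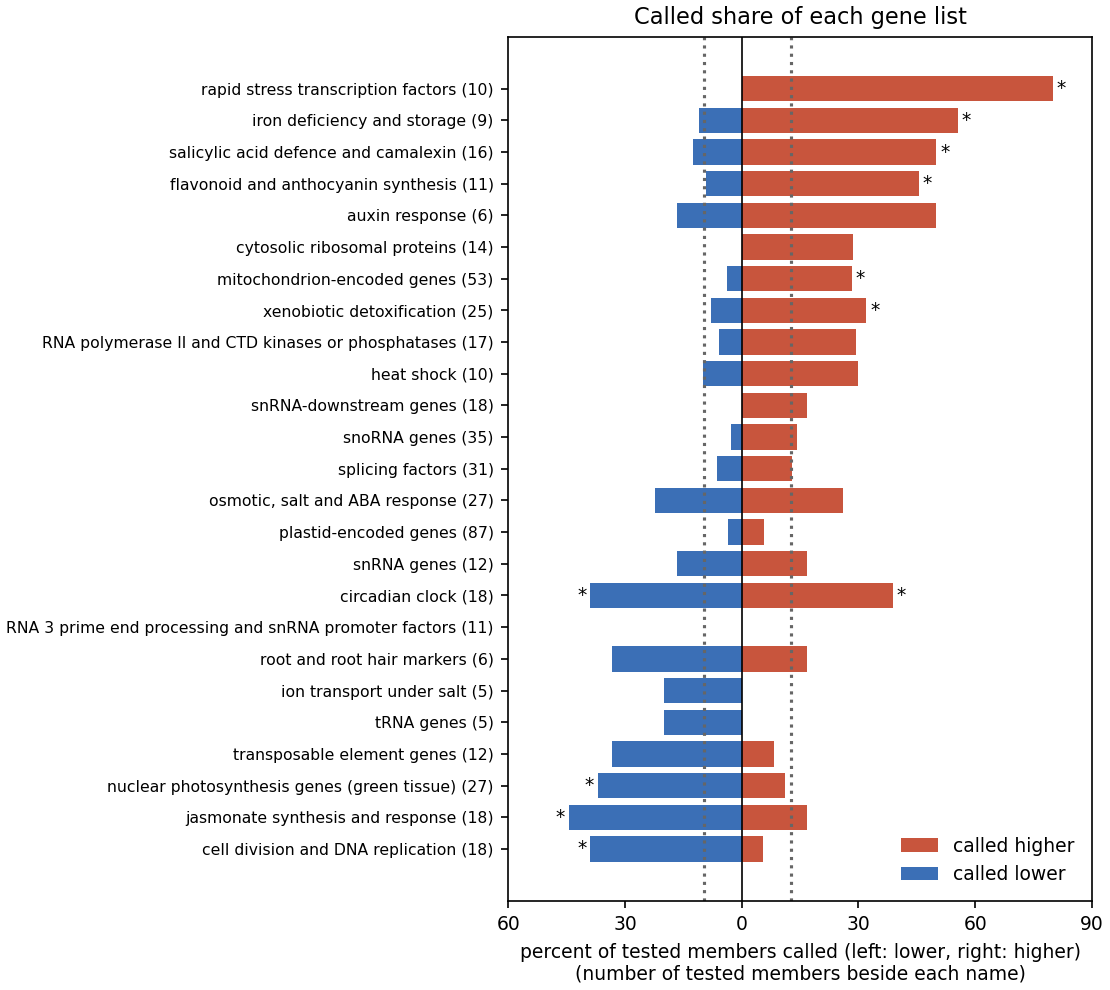
Percent of tested members called higher (right) and lower (left) in the labelled knockdown for each list with at least 5 tested members, from the authors' deposited table; stars mark Fisher's exact tests with adjusted p under 0.05 and dotted lines the share over all tested genes, 12.7% higher and 9.78% lower. Rapid stress transcription factors reach 80.0% higher, and jasmonate genes 44.4% lower.

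Of 20159 tested start groups, 3532 were called, 2052 higher and 1480 lower, in the authors' deposited table. Of the 4060 called genes, 3489 had a start group called in the same direction, 571 had no called start group, and 31 genes were called at start group level alone. A gene with 1 start group has the same values in both tables, so most of this overlap was fixed in advance. Of the 444 called genes with at least 2 tested start groups, 172 had one called in the same direction. Among 1900 genes with at least 2 tested start groups, 1 had start groups called in opposite directions. This was EER4 (AT1G17440, chromosome 1, 5982267 to 5987784), a gene of ethylene signalling, with start groups going from 2.99 to 10.3 FPKM (q = 0.0167) and from 8.11 to 1.66 FPKM (q = 0.00873) in the authors' deposited table. CPL4 had a single start group. The limma, permutation and Cuffdiff p-values here measure the spread between these 6 libraries only, while Fisher's exact tests compare counts of genes, which are not independent replicates.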

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

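Settings with a pseudocount of 50, separate fits of either kind of region, depth relative to the own snRNA and the omission of atU5-13 were chosen after seeing the data. Over the alternatives run for results that answer a comparison, 85 of 108 stayed within a tolerance, and 300 of 316 values of named regions kept direction and side of the threshold. The tolerance was a set ratio for counts, so that 22 calls against 32 passed. For means it was the larger group SD, and for Fisher's exact tests of snRNA-downstream genes the same side of the threshold. The 15 extensions called higher became 8 with the replicate block and 29 of 75 when each extension was divided by its own snRNA, a count that also holds falls of the snRNA, since 3 of the 29 had no reads in any library; leaving out 1 library gave 11 to 20. The 17 lower snRNA regions became 2 after median-ratio scaling, which centres the snRNA regions by construction, and 5 with the replicate block, and 5 to 25 without 1 library; all calls went from 32 to 13 with the block and ranged from 17 to 37 without 1 library. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.0707, 0.0337 and 0.0293, each the best match of its library, a hint from the data and not from the design, and below the 0.1 set for pairing. The block leaves fewer degrees of freedom, and atU4.1's extension then had a limma adjusted p = 0.0551, the highest of its alternatives, which began at 9.90e-04. Without wild type replicate 1, 1 extension was called lower, in no other setting. The mean log2 difference of the extensions was 3.72 and 1.78 with pseudocounts of 0.1 and 10, by their construction, and 4.2 without the regions of lowest mean depth; it ranged from 2.52 to 3.23 without 1 library. That of the snRNA regions was −0.31 after median-ratio scaling and −2.17 to −0.95 without 1 library. atU5-8, atU5.1b and atU5-7 were not past the threshold after median-ratio scaling (limma adjusted p = 0.106, 0.139 and 0.495, the highest of their alternatives, which began at 3.48e-04, 7.48e-04 and 0.00196). Of uncalled regions, atU2.5 and atU2.7 turned to 1.01 and 1.16 after that scaling. It divides by 1.62 to 2.48 in wild type and by 0.252 to 1.31 in the labelled knockdown, and so raises every labelled-knockdown library relative to wild type. atU2.7 ranged from −1.0 to 0.047 without 1 library, the latter without labelled-knockdown replicate 3, and the cause was not tested. The atU5-13 extension turned to −0.47 relative to its own snRNA. Both its regions had equal depth per base wherever there were reads. The value thus comes almost wholly from libraries without reads, where pseudocount and region length set the ratio. Called genes fell from 4060 to 2480 at q under 0.01 and to 1035 with a 2-fold minimum, start groups from 3532 to 2155 and 967, and shared calls from 3489 to 2135 at q under 0.01, as stricter criteria must. Of 12 list tests past the threshold, 5 remained in number with FPKM of at least 5, which tests fewer genes. With a 2-fold minimum the CPL, photosynthesis and cell division calls, and those of mitochondrion-encoded genes, had an adjusted p = 1 in Fisher's exact test, and the lower clock calls 0.768. snRNA-downstream genes had p = 1 at q under 0.01, as did genes upstream on the same strand, in both cases with a smaller share called higher than elsewhere; the other windows and controls lay on the same side as the main p of 0.493. Extensions with low sums rest on very few reads. Over the 123 regions simulated with 1 common spread, unlike the real ones, the test recovered 14.7% of changes of 3 on the log2 scale.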

Other observations

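The tests of snRNA depth, short fragments, exchanged libraries, transgene reads and library splits were chosen after their results were seen, and the 4 added gene lists and the other clock-controlled genes were drawn up after the largest changes and the clock list had been seen, leaving out genes seen there. Aliphatic glucosinolate synthesis, a defence pathway of the cabbage family, fell almost throughout in the labelled knockdown. Of 16 tested genes besides AOP2, 15 were called lower and 0 higher, and 16 lower when adjusted over the list alone (Fisher's exact test over the added lists, adjusted p = 3.98e-14). The regulators MYB28 (from 32.4 to 21.0 FPKM) and MYB29 (from 13.9 to 6.17 FPKM) and the enzymes CYP79F1 (log2 ratio −1.65), CYP83A1 (from 129 to 43.0 FPKM) and BCAT4 (from 111 to 31.3 FPKM) fell in the authors' deposited table. MAM3 was the exception, at 9.83 and 7.93 FPKM (q = 0.147) in the authors' deposited table. The test is in line with a change of the whole pathway, as a hypothesis.

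Phosphate starvation genes were called lower more often than other tested genes, with 9 of 13 called lower and 0 higher, and 9 lower when adjusted over the list alone (adjusted p = 8.00e-07). SPX1 went from 26.6 to 7.73 FPKM, MGD3 from 4.66 to 1.16, PS2 from 3.94 to 0.533 and the sulfolipid gene SQD2 from 38.0 to 21.4 FPKM in the authors' deposited table. Genes of the mitochondrial stress response were called higher more often, 7 of 10 with 0 lower, and 9 when adjusted over the list alone (adjusted p = 6.02e-05). The alternative oxidase gene AOX1A rose from 31.1 to 108 FPKM, OM66 from 1.49 to 15.3, SOT12 from 5.57 to 25.7 and the regulator NAC013 from 2.04 to 9.33 FPKM in the authors' deposited table. DNA damage genes, tested because NAC044 was among the largest rises, were called higher in 3 of 14 with 0 lower, and 3 when adjusted over the list alone (adjusted p = 0.408), so the wider group did not pass.

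CPL4 was listed higher, not lower, in the labelled knockdown. An exchange of single libraries between the groups is argued against, since the lowest extension sum of a labelled-knockdown library was 8.99 times the highest of a wild type library, leaving no library out of place in either group. Reads from the silencing transgene counted as CPL4 may raise its FPKM, but CPL4 had 1 tested start group and the deposited values give no depth along the gene, so this cannot be told apart from a true rise. An exchange of both whole groups, or a rise of CPL4 in these plants, was not tested.

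Where snRNA depth was lower in the labelled knockdown, a lower depth of those libraries for every region alike is argued against for U6: the log2 ratio of U6 to U2 depth within a library, which no scaling changes, differed by −2.49 between the group means, with 0.28 ± 0.23 in wild type and −2.22 ± 0.48 in the labelled knockdown (SD, n = 3; exact permutation p = 0.1). Loss of short fragments could also lower U6, and likewise U5 and U4, all shorter snRNAs, more than U2. The family medians of the log2 difference were −3.2 for U6 (median length 102 bp) and −3.3 for U5 (126 bp). They were −2.1 for U4 (154 bp), −1.9 for U1 (165 bp) and −0.73 for U2 (196 bp). The small families, with 1 or 2 regions each, broke this order of length. They stood at −1.40 for U6atac (121.5 bp), −1.59 for U11 (130 bp), 1.27 for U12 (147 bp) and −0.84 for U4atac (159 bp). The single U6 copy atU6-5 (101 bp) stood at −0.54. None of these regions was past the limma threshold. The 28 tested short snoRNA genes had a median log2 ratio of 0.27 in the authors' deposited table, with a bootstrap interval from −0.38 to 0.90, far from a fall of the size seen for U6. This still cannot be told apart, since 5 of the 28 were listed at 0 in the labelled knockdown and FPKM of such short genes rests on a fragment length model that can offset a loss of short fragments. A lower level of mature snRNAs in these plants stays open too, and for U1 and U2 the lack of library totals leaves no direction.

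Clock genes moved in both directions. In a test on clock-controlled genes outside the fixed list, 8 of 11 morning genes had a log2 ratio above 0 and 7 of 7 evening genes one below 0, called or not (Fisher's exact test on these signs, p = 0.00402). Of them 6 morning genes were called higher and 6 evening genes lower, for example CAT2 (from 169 to 456 FPKM) and GRP7 (from 824 to 331 FPKM) in the authors' deposited table, and 1 morning gene, RVE2, was called lower. That is consistent with an earlier phase of the day in the labelled knockdown. Harvest at another hour and a shifted clock predict the same values and cannot be told apart here. How far calls in the other gene lists follow the same difference in phase was not tested.

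Of the 10 splits of the 6 libraries into equal groups, 1, the real one, called as many as 32 regions, and the highest other split called 2. Splits of 3 against 3 are too few for a share under 0.05.

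atU5-13 (chromosome 5, 21812656 to 21812785, in the loci of AT5G53740 and AT5G53742 on the opposite strand) had a mean depth of exactly 693 per base over both its snRNA region and its extension in labelled-knockdown replicate 1, 1250 in replicate 2, 1 in wild type replicate 1 and 0 in the other libraries. The 2 regions adjoin and span 130 and 50 bp, while reads were 100 bp long. Equal whole-number means in each library with reads argue against reads that begin or end within them. What produced this depth was not tested. AT1G61280, a tested snRNA-downstream gene 298 bp after atU12, was listed at 0.651 FPKM in wild type and 51.4 FPKM in the labelled knockdown, with q = 0.110, in the authors' deposited table. The extension of atU12 itself rose from 105 ± 39.5 to 2243 ± 893 (SD, n = 3; limma adjusted p = 0.00584), and its limma adjusted p ranged from 0.00336 to 0.157 over the alternatives, the highest when divided by its own snRNA depth. AT1G70185, whose locus holds atU5-3, was called higher, from 1.57 to 8.30 FPKM (q = 0.0492), in the authors' deposited table. NDB4, called neither way, was listed at 0.0438 FPKM in wild type and 3.10 FPKM in the labelled knockdown in the authors' deposited table.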
